A study of Mus musculus with 14 samples.

How the data were processed

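Bulk RNA was sequenced from lung and from gastrocnemius, a calf muscle, of male C57BL/6 mice aged 6 to 8 weeks, in a model that delivers cells of a line named KrasIKKaL into the airways through the trachea, per the labels' protocols. The 14 libraries were made with a strand-preserving kit (MGIEasy RNA Directional) and read at 100 bases, per the labels. Titles sort them into 4 groups, read here as control (CON) and tumour-bearing (TB): 3 control and 3 tumour-bearing muscle libraries, 3 control and 5 tumour-bearing lung libraries. What the control mice received is not given in the sources used here. Nor do the labels say that libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical.

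Reads were trimmed with Trim Galore, aligned with STAR 2.7.9a and counted with RSEM 1.3.3, as the submitters' processing notes name these tools. The tools' settings, the strand option of the counting and the genome build are not given in the sources used here, so no coordinates are reported. For each library the authors deposited a table of 55416 genes by Ensembl identifier, with RSEM expected counts, which are estimates and need not be whole, and TPM, abundances of transcripts after division by effective length and scaling to a common total. Of the 55416 values of a library, listed to 2 decimals and with those at 0 included, 6.28% to 11.9% had decimals other than 00. Expected counts were rounded to whole numbers for the tests, and the deposited TPM entered only 1 alternative, as log2(TPM + 1). RSEM splits reads that map to several genes, so values of near-identical copies, such as the Prl2c, granzyme and H2-Q genes, are uncertain. So are those of mitochondrial genes with nuclear copies. Symbols came from a table of mouse identifiers, which matched 52083 of the 55416 (94.0%) and left 3333 without a symbol.

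Total counts per library ran from 32476194 to 44169410 in muscle and from 47947363 to 61087315 in lung. A count of 0 allows up to 3 counts in a library, or 0.0491 to 0.0924 counts-per-million (CPM), and intervals and floors of this kind cover counting error only. Every pair of replicates differed by far more than sampling noise, with chi-square per degree of freedom from 21.3 to 480, so no library was treated as a duplicate.

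Each tissue was fitted on its own in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr for low counts, glmQLFit and the two-sided quasi-likelihood test glmQLFTest), and p-values were adjusted by Benjamini-Hochberg over the genes tested with a threshold of 0.05. Adjusted p-values below come from this test unless another is named. Standard errors (SE) of log2 fold changes were taken as the absolute change divided by the square root of the F statistic. Changes given without a unit are log2 fold changes of tumour-bearing over control. CPM are relative to TMM-scaled library sizes and given as mean ± SD. The interaction of tissue and tumour was tested in 1 fit of all 14 libraries. Calls in both tissues were compared with the number that independent lists of the same sizes would share (n1 × n2 / N), and fold changes by correlation across genes, which are not independent replicates.

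Before the data were examined, 21 pathway lists, 18 lists of cell type markers and 2 lists of quality genes were fixed (41 lists, 697 genes, 696 of them found), as were the designs, the alternatives and the rule for named genes. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of that tissue, and again with the correlation estimated from the residuals. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. A further 5 lists, on Y-linked genes, gut and liver epithelium, cytosolic ribosomal proteins, proteasome subunits and clock genes, were chosen after the data were seen.

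The rule for named genes took, in each tissue, Ctsl, the 4 largest positive and 4 largest negative log2 fold changes among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a clone, a predicted gene or a receptor segment, the 2 members with the smallest unadjusted p of each pathway list assigned to that tissue or to both, and 1 such member of each marker or quality list. For both tissues it took the 4 genes higher in both and the 4 lower in both with the smallest maximum adjusted p, and the 3 genes each way with opposite calls that also passed the interaction, with the interaction given for Ctsl and for genes named in both tissues. Other genes, among them members of lists with 5 or fewer calls, are marked as named after their values were seen.

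Alternatives were DESeq2's size factors (RLE) and upper-quartile scaling in edgeR, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), no filter, a mean of at least 1 CPM, all 14 libraries in 1 fit, the robust quasi-likelihood fit, the replicate number as a block, and leaving out each library in turn. For the lists, they were the estimated correlation, fry, RLE, the filter at 1 CPM, the block and leaving out libraries. A fit without mitochondrial genes and their nuclear copies was added after the data were seen. Counts with 100 genes changed at each of 2 known folds were simulated from the real means: the muscle test recovered 2% of 2-fold and 62% of 4-fold changes among 14132 genes, the lung test 11% and 77% among 18871, and the interaction 0% and 19% among 19409. False calls were 5.88%, 5.38% and 5% of those made. Camera called 2 of 2 changed lists of 20 genes and 0 of 40 unchanged ones in each tissue, in simulations without correlation between genes.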

Results

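The series looked for targets relevant both to cachexia, the loss of muscle mass in cancer, and to immune-related adverse events of muscle, and its title names cathepsin L. Expression was measured by RNA sequencing in lung, where the injected cells were delivered, and in gastrocnemius. The 3 control muscle libraries held 36546828, 33379733 and 32476194 counts and the 3 tumour-bearing muscle libraries 44169410, 35025808 and 33199782. In lung, the 3 control libraries held 55987871, 54605155 and 50157111 counts and the 5 tumour-bearing libraries 61087315, 52605547, 59019746, 51632852 and 47947363. Tissue labels were checked on marker genes in unscaled CPM. Sftpc, the surfactant protein C gene of alveolar type 2 cells, had 14870 ± 1296 CPM in control lung (n = 3) and was listed at 0 in all muscle libraries. Acta1, skeletal muscle actin, had 28590 ± 8884 CPM in control muscle (n = 3) and at most 0.399 in any lung library. Sftpc was far lower in tumour-bearing lung, at 220 ± 230 CPM (n = 5).

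In muscle, the question was which genes differ between tumour-bearing and control mice (n = 3 and 3). In tumour-bearing muscle, 11 of 18 atrophy and ubiquitin genes, 8 of 22 autophagy genes, 11 of 17 glucocorticoid response genes and 6 of 12 interleukin-6 genes were higher. Of 24 collagen and matrix genes, 13 were lower. These 5 lists passed in camera at the preset correlation but not with an estimated one (adjusted p from 0.692 to 0.823), and the autophagy, glucocorticoid and interleukin-6 lists did not pass in fry. Trim63 and Fbxo32, the muscle ubiquitin ligases MuRF1 and atrogin-1, were 12.7-fold and 8.03-fold higher. Mt1, a metallothionein that binds metals, went from 47.7 ± 13.2 to 1588 ± 1145 CPM, and Col1a1, a chain of type I collagen, from 198 ± 106 to 5.69 ± 2.52 CPM. Of 14373 genes tested, 1226 were higher and 970 lower (2196 in all, 15.3%), and 5126 had an unadjusted p below 0.05. In 6191 genes (43.1%) the groups did not overlap, against the 10% that chance gives for 3 against 3. The count depended on single libraries: it was 243, 141 and 106 without control 1, 2 or 3, and 1432, 4513 and 1129 without tumour-bearing 1, 2 or 3. Upper-quartile scaling, which moved the median of all genes to -0.25, gave 760 higher and 1079 lower genes, and limma on log2(TPM + 1) gave 157 and 258.

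The atrophy and ubiquitin list mixes ubiquitin ligases and proteasome subunits with other genes of muscle wasting. Of its 18 genes, 11 rose and the other 7 did not pass (16 rose adjusted over the list alone), with a median log2 change of 1.95. The list passed in camera (adjusted p = 1.67e-08), though not with the correlation estimated from the residuals (adjusted p = 0.692 with an estimated correlation). Eif4ebp1, an inhibitor of cap-dependent translation (ENSMUSG00000031490), rose from 47.2 ± 2.98 to 745 ± 216 CPM (log2 change 3.98, SE 0.34, adjusted p = 0.00407). Gadd45a, a growth arrest gene induced by stress, rose 8.45-fold (adjusted p = 0.00636). Trim63 (log2 change 3.66, SE 0.65, adjusted p = 0.0141) and Fbxo32 (SE 0.52, adjusted p = 0.0130) were named after their values were seen, and tumour-bearing libraries ranged from 367 to 2500 CPM for Trim63. Of 22 autophagy and lysosome genes, 8 rose and 14 did not pass (15 rose adjusted over the list alone, median 0.93, camera adjusted p = 6.09e-06, adjusted p = 0.692 with an estimated correlation). Map1lc3b, which encodes the autophagosome protein LC3B, rose 4.54-fold (adjusted p = 0.00715), and Bnip3, a receptor for the autophagy of mitochondria, changed by 2.24 (SE 0.45, adjusted p = 0.0177). Every gene of this paragraph had all 3 tumour-bearing values above all 3 control values. The call of Map1lc3b was lost without control 2 or 3 and that of Bnip3 without any 1 of the controls (adjusted p up to 0.0541 and 0.0811), that of Bnip3 also on log2(TPM + 1) (0.0630), and the calls of Trim63 and Fbxo32 were not rerun under the alternatives.

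Among lysosomal cathepsins in muscle, Ctsl, which encodes the cysteine protease cathepsin L (ENSMUSG00000021477), rose 6.10-fold, from 36.4 ± 6.56 to 222 ± 189 CPM (log2 change 2.61, SE 0.57, adjusted p = 0.0233). Its 3 tumour-bearing values, from 76.2 to 435 CPM, all lay above the controls. Ctso, cathepsin O, was the only other of 11 cathepsins to pass, at -1.11 (SE 0.32, adjusted p = 0.0484, lower in all 3 tumour-bearing libraries). Adjusted over the list alone, 2 were higher and 2 lower. The list as a whole had a median of 0.23 (camera adjusted p = 0.599), which upper-quartile scaling turned to -0.01. The Ctsl call was lost without control 1, 2 or 3 (adjusted p = 0.0737, 0.0858 and 0.112) and on log2(TPM + 1) (0.105), and without tumour-bearing 1 the log2 change was 1.69. The Ctso call was lost without any 1 of the controls or tumour-bearing 1 or 3, with adjusted p up to 0.169 (without control 3), and on log2(TPM + 1) (0.287).

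Genes that respond to glucocorticoid hormones formed a second group that was higher in tumour-bearing muscle, with 11 of 17 members past the threshold and 6 not (13 rose adjusted over the list alone, median 1.89). Camera gave adjusted p = 3.00e-06, and adjusted p = 0.823 with an estimated correlation. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 11.5-fold (log2 change 3.52, SE 0.43, adjusted p = 0.00604), and Glul, glutamine synthetase, 5.85-fold (2.55, SE 0.29, adjusted p = 0.00587). Mt2, the second metallothionein, rose 33.5-fold, close to Mt1 at 33.3-fold (adjusted p = 0.00715 and 0.00718). Of 12 interleukin-6, STAT3 and acute phase genes, 6 rose and 6 did not pass (9 rose adjusted over the list alone, median 1.29, camera adjusted p = 7.10e-05, adjusted p = 0.692 with an estimated correlation). Lcn2, the siderophore-binding lipocalin 2, rose from 1.24 to 46.1 CPM (adjusted p = 0.00718), and Il6ra, the interleukin-6 receptor, 10.3-fold (adjusted p = 0.00935). In the myostatin, activin and TGF-beta list, 3 of 19 genes rose, 3 fell and 13 did not pass (4 and 4 adjusted over the list alone, median 0.28, camera adjusted p = 0.614). Acvr1b, an activin type I receptor, rose by 2.52 (SE 0.52, adjusted p = 0.0194) while Inhba, the activin A subunit, fell by 2.47 (SE 0.56, adjusted p = 0.0246). Named after their values were seen, Mstn, which encodes myostatin, and Inhbb also rose, and Gdf11 and Acvr2b, an activin type II receptor, fell. All of these genes separated the groups completely. Calls of Mt1, Lcn2 and Il6ra were lost without control 3 (adjusted p = 0.0502, 0.0541 and 0.0636), and those of Acvr1b and Inhba without any 1 of the controls (up to 0.0999 and 0.108), that of Inhba also without tumour-bearing 1 or 3. The change of Inhba was -1.85 without control 3, and that of Acvr1b 1.87 without tumour-bearing 1. The calls of Il6ra, Acvr1b and Inhba were also lost on log2(TPM + 1) (adjusted p = 0.0730, 0.0981 and 0.119).

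Matrix genes went the other way. Of 24 collagen and matrix genes 13 fell and 11 did not pass (16 fell and 1 rose adjusted over the list alone), with a median of -1.60 (camera adjusted p = 4.12e-08, adjusted p = 0.692 with an estimated correlation). Fbn1, the microfibril protein fibrillin 1, fell by 3.07 on the log2 scale (SE 0.26, adjusted p = 0.00407). Col6a2, a chain of type VI collagen, fell from 43.6 to 6.09 CPM (SE 0.27, adjusted p = 0.00425), and Col1a1 was 34.9-fold lower (SE 0.55, adjusted p = 0.00496). In the fibroblast marker list 9 of 14 genes fell, also adjusted over the list alone, and 5 did not pass (median -2.12, camera adjusted p = 6.09e-06, adjusted p = 0.692 with an estimated correlation). Thy1, a surface glycoprotein of fibroblasts and T cells, fell by 3.16 (SE 0.33, adjusted p = 0.00496). Fibroblast markers that are not matrix genes had a median of -0.56. Other large decreases were Nrep, linked to nerve regeneration (63.5 to 1.24 CPM, adjusted p = 0.00424), and Kera, the matrix proteoglycan keratocan (log2 change -5.67, SE 0.97, adjusted p = 0.0129). The rule also named Ccdc152 (-5.48, SE 1.61, adjusted p = 0.0495). The largest increase under the rule was that of Doc2b, a calcium sensor of vesicle release, from 0.159 to 16.1 CPM (adjusted p = 0.00992). Groups did not overlap for any of these genes, which the rule required of the largest changes. Without control 3 the calls of Doc2b and Kera were lost (adjusted p = 0.0647 and 0.0553), and that of Ccdc152 was lost without any 1 of the 6 libraries (up to 0.290). Ccdc152 rests on control 3, with 36.5 CPM against 0.494 and 1.56 in controls 1 and 2, and its log2 change was -1.81 without control 3, -4.82 without tumour-bearing 1 and -6.22 without tumour-bearing 2. Kera had -4.50 without control 3 and -5.06 without tumour-bearing 1, Nrep -6.42 without tumour-bearing 2, and Doc2b 7.25 without control 1. Both Doc2b (0.0533) and Ccdc152 (0.208) also lost their calls on log2(TPM + 1). Ccdc152 lost its call also with upper-quartile scaling, limma-voom, a mean of at least 1 CPM and the robust fit (adjusted p from 0.0509 to 0.195).

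Contractile and metabolic genes showed few calls. In the fast fibre list 2 of 16 genes rose, 1 fell and 13 did not pass (3 and 2 adjusted over the list alone), and median (0.17) and mean (-0.09) differed in sign under an upward test (camera adjusted p = 0.667). Actn3, the fast fibre Z-disc protein alpha-actinin 3, rose from 2862 to 6894 CPM (adjusted p = 0.0332), and Atp2a1, the fast fibre calcium pump SERCA1, from 7578 to 19828 CPM (adjusted p = 0.0348). Upper-quartile scaling ended both calls and turned the list's median to -0.03. Casq1, calsequestrin 1, fell, and was named after its value was seen. None of 16 slow fibre genes passed in edgeR (5 lower at an unadjusted p below 0.05, 5 lower in DESeq2, 0 in limma-voom, 5 lower adjusted over the list alone, median -0.56, camera adjusted p = 0.425, past the threshold without control 3). Casq2, calsequestrin 2, had a log2 change of -1.69 (SE 0.50, adjusted p = 0.0523) and Mb, myoglobin, -1.51 (SE 0.46, adjusted p = 0.0553). Of 15 denervation and junction genes Runx1, a transcription factor that denervated muscle induces, rose by 2.81 (adjusted p = 0.0263), while Lrp4, the agrin receptor of the junction, fell by 1.53 (adjusted p = 0.0320), as did Myh8, perinatal myosin, named after its value was seen. These 3 also passed adjusted over the list alone (median -0.43, camera adjusted p = 0.596). The oxidative phosphorylation list was lower as a set, with a median of -0.55 (camera adjusted p = 0.000339, adjusted p = 0.823 with an estimated correlation), though just 2 of 46 genes fell and 44 did not pass. Adjusted over the list alone edgeR called 0 of them (8 lower at an unadjusted p below 0.05, 4 lower in DESeq2, 2 in limma-voom). Those 2 were Cyc1, cytochrome c1 (log2 change -1.26, adjusted p = 0.0363), and Cycs, cytochrome c (-1.13, adjusted p = 0.0402). Mitochondrially encoded RNA took 25.6 ± 9.02% of control and 20.2 ± 3.39% of tumour-bearing counts. The 13 mitochondrially encoded genes gave 0 calls in edgeR, also adjusted over the list alone (2 lower at an unadjusted p below 0.05, 2 in DESeq2, 0 in limma-voom, median -0.34, camera adjusted p = 0.551, past the threshold without control 1), and mt-Co2, a subunit of complex IV, had a log2 change of -1.54 (adjusted p = 0.0652). In fatty acid oxidation, Acot1, an acyl-CoA thioesterase, rose by 2.90 (adjusted p = 0.0167), Pdk4, named after its value was seen, rose, and Acaa2, a thiolase, fell by 1.34 (adjusted p = 0.0338), also adjusted over the list alone, and 22 did not pass (median 0.15, -0.08 under upper-quartile scaling, camera adjusted p = 0.601). Genes past the threshold here did not overlap between groups, and each named by the rule lost its call without any 1 of the controls (adjusted p up to 0.0777 for Acot1 and 0.151 for Atp2a1). Calls of Actn3, Atp2a1, Runx1, Cyc1, Cycs and Acaa2 were also lost without tumour-bearing 3, and those of Runx1, Lrp4 and Acaa2 without tumour-bearing 1. All of these but Acot1 lost their calls on log2(TPM + 1) (adjusted p from 0.0526 for Acaa2 to 0.348 for Cyc1). So did Runx1 in limma-voom (0.0615) and Lrp4 and Atp2a1 in 1 fit of all libraries (0.0539 and 0.0734). Casq2, Mb and mt-Co2 passed in DESeq2, with no filter and with the replicate block (adjusted p up to 0.0447 for Mb). Casq2 passed also with upper-quartile scaling and at a mean of at least 1 CPM, and Mb without tumour-bearing 2 (0.0385).

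Interferon genes were lower in muscle with 1 exception among the calls. Of 23 interferon response genes 4 fell, 1 rose and 18 did not pass (10 fell and 1 rose adjusted over the list alone), with a median of -1.24 (camera adjusted p = 5.31e-05, adjusted p = 0.823 with an estimated correlation). Cxcl10 and Cxcl9, chemokines that attract T cells and are induced by interferon gamma, moved apart: Cxcl10 rose by 4.07 (SE 0.53, adjusted p = 0.00673) and Cxcl9 fell by 2.43 (SE 0.55, adjusted p = 0.0252). Gbp3, Gbp7 and Usp18, interferon-induced genes named after their values were seen, also fell. Of 15 genes of MHC class I presentation 5 fell and 10 did not pass (6 fell adjusted over the list alone, median -0.66, camera adjusted p = 0.00503, adjusted p = 0.823 with an estimated correlation). They were the immunoproteasome subunits Psmb8, Psmb9 and Psmb10 and the near-identical H2-Q6 and H2-Q7, all named after their values were seen. Neutrophil markers were higher, with 4 of 5 genes past the threshold, also adjusted over the list alone (median 2.48, camera adjusted p = 0.0117, adjusted p = 0.692 with an estimated correlation). S100a9, a calprotectin subunit, rose by 2.48 (SE 0.43, adjusted p = 0.0130), as did S100a8, Retnlg and Il1r2, named after their values were seen. A list of alveolar macrophage markers also passed in muscle, where 3 of 6 genes rose (4 adjusted over the list alone, median 1.28, camera adjusted p = 0.0214, adjusted p = 0.692 with an estimated correlation, and not past the threshold without tumour-bearing 2). They were Chil3, Ear2 and Car4, named after their values were seen. Macrophage and monocyte markers split, with 2 of 18 higher, 2 lower and 14 not past (2 and 3 adjusted over the list alone), a median of -0.08 and a mean of 0.01 that differed in sign under a downward test (camera adjusted p = 0.601). Gpnmb, a glycoprotein of lysosomes, rose by 3.02 (SE 0.66, adjusted p = 0.0226), Cd68 rose with overlapping groups, and Aif1 and Ms4a7 fell, the last 3 named after their values were seen. Too few lymphocyte markers were tested for camera: Cd3e, of the T cell receptor complex, went from 159 to 7 counts over 3 libraries (adjusted p = 0.0190) and was the 1 call among 3, and Cd79b, of the B cell receptor, fell by 2.71 (adjusted p = 0.0211) while Xbp1 rose, among 4. These counts were the same adjusted over the list alone, and Xbp1 was named after its value was seen. All genes named by the rule here separated the groups. Calls of Cxcl9, S100a9, Gpnmb, Cd3e and Cd79b were lost without any 1 of the controls (adjusted p up to 0.113, 0.0846, 0.0891, 0.0861 and 0.0948), and those of Gpnmb without tumour-bearing 1 or 3 and of Cxcl9 without tumour-bearing 3. The change of Cd3e was -3.80 without tumour-bearing 1, and tumour-bearing 2 held all 7 of its tumour-bearing counts. The Cxcl10 call was kept without each of the 6 libraries. The calls of Cxcl9 and Gpnmb were also lost on log2(TPM + 1) (adjusted p = 0.574 and 0.102), that of Cxcl9 in 1 fit of all libraries (0.142) and that of Gpnmb in limma-voom (0.0514).

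Other resident cell types of muscle showed mixed changes. Of 11 satellite cell markers 2 rose, 3 fell and 6 did not pass (3 and 4 adjusted over the list alone, median -0.56, camera adjusted p = 0.539). Cdh15, the satellite cell adhesion protein M-cadherin, rose by 1.88 (SE 0.27, adjusted p = 0.00774) and so did Des, while Pax7, the transcription factor of satellite cells, Chodl and Notch3 fell, all but Cdh15 named after their values were seen. Among 11 adipocyte genes Pnpla2, the triglyceride lipase ATGL, rose by 2.45 (SE 0.40, adjusted p = 0.0115), Plin1 and Thrsp, named after their values were seen, fell, and 8 did not pass (1 higher and 3 lower adjusted over the list alone, median -1.12, camera adjusted p = 0.403, past the threshold without control 1 or tumour-bearing 3). Of 15 endothelial genes 1 passed: Kdr, the VEGF receptor 2, fell by 1.16 (SE 0.32, adjusted p = 0.0438). Adjusted over the list alone edgeR called 0 (2 lower at an unadjusted p below 0.05, 1 in DESeq2, 1 in limma-voom, median -0.20, camera adjusted p = 0.551). None of 12 Schwann cell and nerve genes passed in edgeR, also adjusted over the list alone (1 lower at an unadjusted p below 0.05, 1 in DESeq2, 0 in limma-voom, median -0.80, camera adjusted p = 0.539, past the threshold without control 1), with S100b at -2.22 (SE 0.77, adjusted p = 0.0784). Of 8 erythroid genes Tfrc, the transferrin receptor, fell by 2.94 (SE 0.47, adjusted p = 0.0110) and the other 7 did not pass (5 higher and 2 lower adjusted over the list alone, median 2.22, camera adjusted p = 0.611), and haemoglobin took 0.626% of counts in tumour-bearing 3. Of 18 immediate early genes 5 rose, 2 fell and 11 did not pass (7 and 3 adjusted over the list alone, median 0.76, camera adjusted p = 0.551). Ier3 rose by 1.88 (SE 0.36, adjusted p = 0.0159), as did Junb, Egr1, Btg2 and Atf3, while Egr3 and Nr4a2 fell, all but Ier3 named after their values were seen and Egr1 and Btg2 with overlapping groups. Calls of Pnpla2, Kdr and Ier3 were lost without any 1 of the controls (adjusted p up to 0.0725, 0.155 and 0.0826), that of Kdr also without tumour-bearing 1 or 2, and that of Cdh15 without control 2 or 3 (up to 0.0594). Kdr, Ier3 and Cdh15 also lost their calls on log2(TPM + 1) (adjusted p = 0.279, 0.0550 and 0.0604), and Cdh15 in 1 fit of all libraries (0.209). S100b passed in DESeq2, with no filter and with the replicate block (adjusted p up to 0.0107). Without tumour-bearing 2 the change of Tfrc was -3.55. Lists fixed for lung alone and not given above did not pass in muscle, with adjusted p from 0.147 for dendritic cell genes to 0.836 for cardiac muscle genes. In all, 11 of 39 lists passed in muscle, 6 higher and 5 lower, 5 passed in fry (not the autophagy, glucocorticoid, interleukin-6, oxidative phosphorylation, interferon and MHC class I lists) and 0 with an estimated correlation, and another split of the 6 libraries gave 15.

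**Figure D1:**
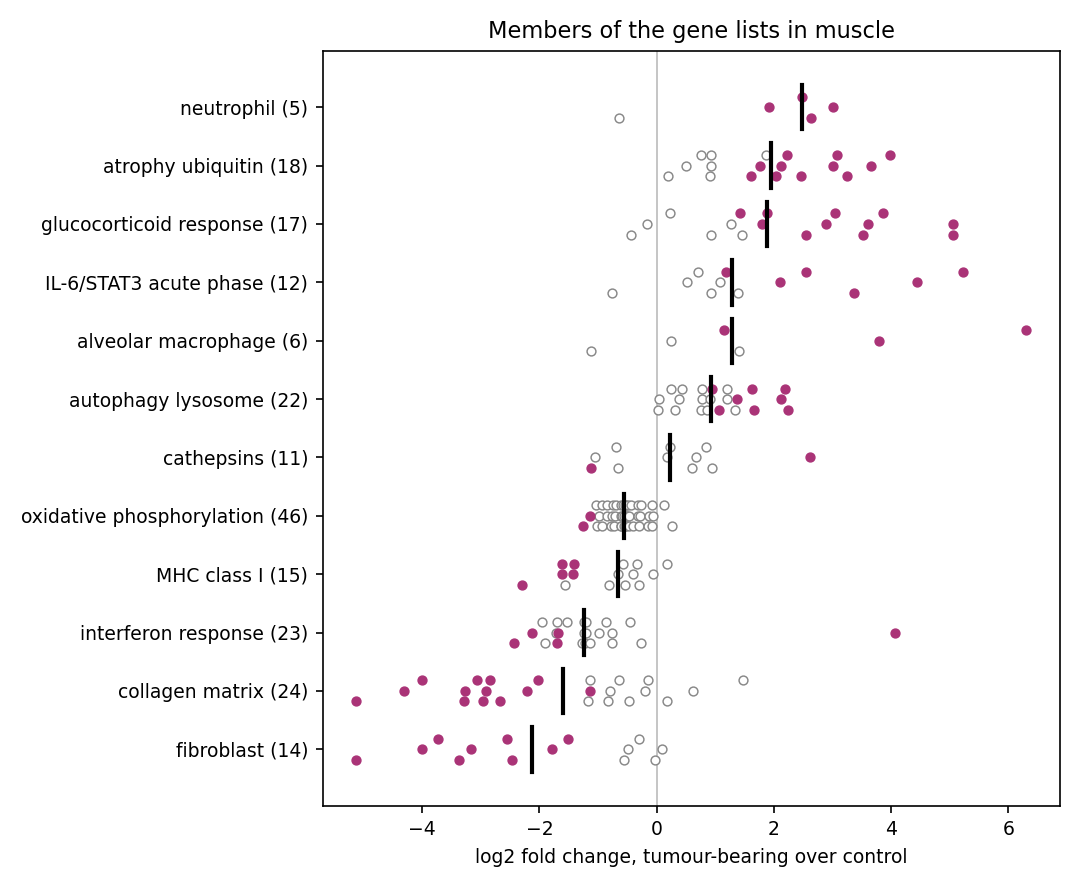
Log2 fold change of tested members of gene lists in muscle, tumour-bearing over control (n = 3 and 3). Only the fixed lists that passed in camera at the preset correlation are shown, with the cathepsin list, which did not pass. Each gene is 1 point, filled where it passed the threshold, with a bar at the median of each list. The atrophy and glucocorticoid lists have medians of 1.95 and 1.89, and the collagen and fibroblast lists of -1.60 and -2.12.

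In lung, tumour-bearing libraries (n = 5) had more RNA of 30 of 30 cell cycle, 20 of 24 glycolysis and hypoxia and 14 of 15 epithelial tumour genes than control libraries (n = 3). They had less RNA of all 12 alveolar type 1, all 14 alveolar type 2, 11 of 15 airway and all 15 endothelial genes. These lists passed in camera at the preset correlation but not with an estimated one (adjusted p from 0.161 to 0.678). Krt18, a keratin of simple epithelia, was 27.0-fold higher, at 5687 ± 1550 against 211 ± 2.26 CPM. Pecam1, the endothelial adhesion molecule CD31, fell from 709 ± 34.6 to 35.9 ± 5.2 CPM. Of 19300 genes tested 5862 were higher and 5651 lower (11513 in all, 59.7%), with 12313 at an unadjusted p below 0.05. The change was over 2-fold for 4203 of the higher and 4895 of the lower genes. On log2(TPM + 1), where the median of all genes was -0.23, limma called 3594 higher and 7994 lower. RNA of 4 Y-linked genes, chosen after the data were seen, was lower in all 5 tumour-bearing libraries of these male mice, and summed to 8.65% of the control level. Every gene named in lung by the rule and past the threshold separated the groups except Irf7. So did 12152 of all lung genes tested (63.0%), and the rule required it of the largest changes. No library changed a lung count of genes by 1.5 times when left out.

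Proliferation and glycolysis genes were higher in lung. All 30 cell cycle genes rose (median 3.18, camera adjusted p = 8.18e-12, adjusted p = 0.650 with an estimated correlation), also adjusted over the list alone. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by 3.84 on the log2 scale (SE 0.28, adjusted p = 9.15e-06), and Ccnb1, cyclin B1, by 4.10 (SE 0.31, adjusted p = 1.26e-05). Of 24 glycolysis and hypoxia genes 20 rose, 3 fell and 1 did not pass, also adjusted over the list alone (median 2.89, camera adjusted p = 1.84e-05, adjusted p = 0.678 with an estimated correlation). Eno1, the glycolytic enzyme enolase 1, rose from 108 to 1521 CPM (SE 0.31, adjusted p = 1.79e-05), and Slc16a3, the lactate exporter MCT4, rose by 4.43 (SE 0.29, adjusted p = 5.44e-06). The 3 that fell were Pfkfb3, Vegfa and Adm, named after their values were seen. Of 46 oxidative phosphorylation genes 38 rose, 1 fell and 7 did not pass (40 and 1 adjusted over the list alone, median 0.94, camera adjusted p = 3.46e-07, adjusted p = 0.650 with an estimated correlation). The 1 that fell was Cox8b, a muscle isoform of a complex IV subunit, named after its value was seen. Among epithelial tumour markers 14 of 15 rose and 1 did not pass, also adjusted over the list alone (median 3.46, camera adjusted p = 1.84e-05, adjusted p = 0.650 with an estimated correlation), among them Krt18 (log2 change 4.75, SE 0.31, adjusted p = 5.98e-06). Cytosolic ribosomal protein genes, chosen after the data were seen, took 2.36 ± 0.0346% of control and 8.37 ± 1.10% of tumour-bearing counts.

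The largest increases under the rule were genes that control lung hardly expressed. Prl2c3 and Prl2c2, near-identical members of the prolactin family, went from 0.0628 to 572 CPM and from 0.0331 to 306 CPM (adjusted p = 0.000453 and 0.000502). Dynap had 1 count over the control libraries and 13432 over the tumour-bearing ones, a ratio of 9113 per library size (95% exact interval 1635 to 359972, adjusted p = 0.000155). Gzme, a granzyme with close paralogs, had 1 and 12658 counts, a ratio of 8588 (1541 to 339231, adjusted p = 0.000757). Largest among the decreases were Pcdhac2, a protocadherin (log2 change -9.86, SE 0.66, adjusted p = 6.06e-06), Cyp1a1, a cytochrome P450 that oxidises foreign compounds (-9.40, SE 0.73, adjusted p = 1.3e-05), Slc7a10, an amino acid transporter (-9.09, SE 0.72, adjusted p = 1.42e-05), and Adra1a, an alpha-1 adrenergic receptor (-9.01, SE 0.60, adjusted p = 6.02e-06). Single libraries moved these changes but ended no call. The log2 change of Prl2c3 was 11.70 and that of Prl2c2 11.62 without tumour-bearing 5 (13.10 and 13.05 with it), and that of Prl2c3 13.91 without control 2. Tumour-bearing 5 held 6234 of the Dynap counts and tumour-bearing 2 held 6505 of the Gzme counts. Their single control counts lay in control 1 (Dynap) and control 3 (Gzme), without which control lung was listed at 0. Pcdhac2 had -10.57 without tumour-bearing 3 and Adra1a -9.64 without tumour-bearing 4. Cyp1a1 had 11 counts in tumour-bearing 3 and at most 1 in the other 4 libraries, against 6540 in control, and Slc7a10 had 5 in tumour-bearing 2 and at most 1 in the others, against 2805.

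Many markers of the lung's own structural cells were lower. All 12 alveolar type 1 genes fell (median -4.80, camera adjusted p = 0.000158, adjusted p = 0.650 with an estimated correlation), and so did all 14 alveolar type 2 genes (median -4.46, the same adjusted p, adjusted p = 0.650 with an estimated correlation). Cav1, caveolin 1, went from 1226 to 129 CPM (SE 0.28, adjusted p = 2.07e-05), and Lpcat1, an enzyme of surfactant lipid synthesis, fell by 3.25 (SE 0.19, adjusted p = 3.4e-06). All 15 endothelial genes fell (median -4.14, camera adjusted p = 5.17e-08, adjusted p = 0.161 with an estimated correlation), with Pecam1 at -4.31 (SE 0.17, adjusted p = 8.26e-07). These 3 counts were the same adjusted over the list alone. Of 15 airway epithelium genes 11 fell, 1 rose and 3 did not pass (11 and 2 adjusted over the list alone, median -6.04, camera adjusted p = 0.00317, adjusted p = 0.650 with an estimated correlation). Ccdc39, needed to assemble motile cilia, fell by 6.85 (SE 0.29, adjusted p = 9.98e-07), while Muc5b, a mucin named after its value was seen, rose with overlapping groups. Of 15 fibroblast genes 7 fell and 8 did not pass, also adjusted over the list alone (median -1.01, camera adjusted p = 0.0135, adjusted p = 0.650 with an estimated correlation), with Mfap4, a microfibril protein, at -5.88 (SE 0.37, adjusted p = 4.47e-06). Erythroid genes fell in 10 of 11 cases, also adjusted over the list alone (median -3.25, camera adjusted p = 0.0108, adjusted p = 0.678 with an estimated correlation), with Alas2, the haem synthesis enzyme of red cell precursors, at -3.34 (SE 0.51, adjusted p = 0.000506). Haemoglobin took 0.695 ± 0.110% of control and 0.0719 ± 0.0488% of tumour-bearing counts. Of 11 cardiac muscle genes 8 fell, 1 rose and 2 did not pass (9 and 2 adjusted over the list alone, median -5.03, camera adjusted p = 0.0335, adjusted p = 0.766 with an estimated correlation), and the list did not pass without tumour-bearing 1 or 4 or with the replicate block. Myl4, the atrial myosin light chain, fell by 5.20 (SE 1.00, adjusted p = 0.0018, -6.81 without tumour-bearing 2), and Ankrd1, named after its value was seen, rose with overlapping groups. Of 11 adipocyte genes 6 fell and 5 did not pass, also adjusted over the list alone (median -1.91, camera adjusted p = 0.0235, adjusted p = 0.650 with an estimated correlation, not past the threshold at a mean of at least 1 CPM). Plin1, the lipid droplet protein perilipin 1, had 272 counts in control and 2 in tumour-bearing lung, 200.5-fold fewer (exact interval 55.0 to 1664, adjusted p = 2.15e-05). Skeletal muscle genes did not pass as a list, with 2 of 8 higher, 5 lower and 1 not past, also adjusted over the list alone (median -1.32, camera adjusted p = 0.513), and Tnni2, fast troponin I, rose from 1.05 to 14.6 CPM (SE 0.32, adjusted p = 1.86e-05), as did Mylpf, named after its value was seen.

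Of 7 lists of immune cells and MHC class II genes, 4 passed as lower in lung and 3 did not pass. The medians of all 7 lay above that of the 4 Y-linked genes of these male mice (-3.59). These decreases therefore do not show that immune cells became a smaller part of the host cells. Of 20 T and NK cell genes 10 fell and 10 did not pass, also adjusted over the list alone (median -1.92, camera adjusted p = 0.00275, adjusted p = 0.765 with an estimated correlation), with the NK cell receptor gene Ncr1 at -6.07 (SE 0.79, adjusted p = 0.000195, with 4 counts in tumour-bearing 3, 2 in tumour-bearing 1 and none listed in the others). Of 14 B and plasma cell genes 9 fell, 1 rose and 4 did not pass, also adjusted over the list alone (median -3.40, camera adjusted p = 0.0266, adjusted p = 0.678 with an estimated correlation). The 1 that rose was Sdc1, syndecan 1, which epithelial cells also express (log2 change 2.01, SE 0.22, adjusted p = 8.5e-05). Alveolar macrophage markers fell in 9 of 13 cases, 1 rose (Plet1, named after its value was seen) and 3 did not pass, also adjusted over the list alone (median -2.05, camera adjusted p = 0.0235, adjusted p = 0.656 with an estimated correlation), with the fatty acid binding protein gene Fabp1 at -6.56 (SE 0.64, adjusted p = 4.15e-05). Of 10 MHC class II genes 5 fell and 5 did not pass (4 fell adjusted over the list alone, median -1.73, camera adjusted p = 0.0382, adjusted p = 0.766 with an estimated correlation), and the list did not pass without tumour-bearing 1, 2, 4 or 5. H2-Ob and H2-Oa, the chains of H2-O, which modulates class II peptide loading, fell by 4.21 and 1.99 (adjusted p = 0.000926 and 0.0168), as did H2-Ab1, Cd74 and Ciita, named after their values were seen, and the H2-Oa call was lost without control 2 or 3 (adjusted p up to 0.0545). Without tumour-bearing 3 the H2-Oa change was -2.65. Dendritic cell genes did not pass as a list, with 6 of 12 lower, 1 higher (Cacnb3, named after its value was seen) and 5 not past, also adjusted over the list alone (median -2.15, camera adjusted p = 0.0552), but did without control 1, tumour-bearing 1 or tumour-bearing 3. Zbtb46, the transcription factor of conventional dendritic cells, fell by 2.85 (SE 0.20, adjusted p = 8.15e-06). Macrophage and monocyte genes had a median of 0.00 (-0.03 with RLE and -0.09 with upper-quartile scaling) and a mean of -0.36, with 2 of 19 higher (Mrc1 and Trem2), 5 lower and 12 not past, also adjusted over the list alone (camera adjusted p = 0.697). Mertk, a receptor for dying cells, fell by 3.32 (SE 0.30, adjusted p = 2.68e-05), as did Lyz2, Ccr2, Adgre1 and Csf1r, named like Mrc1 and Trem2 after their values were seen. Neutrophil genes had 2 higher, 5 lower and 8 not past among 15, also adjusted over the list alone (median -0.65, camera adjusted p = 0.371). Cxcr2, the chemokine receptor of neutrophils, rose by 3.12 (SE 0.41, adjusted p = 0.000205) with Il1r2, while Mpo, Camp, Ngp, Csf3r and Retnlg fell, all but Cxcr2 named after their values were seen.

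Secreted factors, proteases and immune regulators in lung moved both ways. In the list of secreted factors tied to cachexia 7 of 25 rose, 8 fell and 10 did not pass, also adjusted over the list alone, and median and mean (both 0.29) differed in sign from a downward test (camera adjusted p = 0.942). Ctf1, cardiotrophin 1, fell by 3.97 (SE 0.39, adjusted p = 4.27e-05), and Gdf15, a cytokine that suppresses appetite, fell by 3.50 (SE 0.37, adjusted p = 6.25e-05). Named after their values were seen, Spp1, osteopontin, rose from 79.1 to 2994 CPM (adjusted p = 0.000102) and Lif, leukaemia inhibitory factor, from 10.1 to 32.2 CPM (adjusted p = 0.00108), while Il6, interleukin-6, fell by 1.76 (adjusted p = 0.0191). Among 14 cathepsins 4 rose, 2 fell and 8 did not pass, also adjusted over the list alone (median 0.21, camera adjusted p = 0.675). Ctse, the aspartic protease cathepsin E (ENSMUSG00000004552), rose from 1.08 to 205 CPM (SE 0.76, adjusted p = 5.1e-05), Ctsf, cathepsin F, fell by 2.49 (SE 0.30, adjusted p = 0.000129), and Ctsl rose. Ctsd and Ctsz also rose and Ctso fell, all 3 named after their values were seen. Of 17 matrix proteases 8 rose, 4 fell and 5 did not pass, also adjusted over the list alone (median 1.34, camera adjusted p = 0.465). Mmp19 and Mmp2, matrix metalloproteinases, fell by 2.45 and 2.21 (adjusted p = 3.46e-05 and 3.92e-05), as did Mmp3 and Adam17, named after their values were seen. Collagen and matrix genes had 10 of 24 lower, 3 higher (Fn1, Timp1 and Thbs2, named after their values were seen) and 11 not past, also adjusted over the list alone (median -0.81, camera adjusted p = 0.242), with Loxl1, a collagen crosslinking enzyme, at -2.45 (SE 0.26, adjusted p = 7.07e-05). Of 18 complement genes 8 fell, 2 rose (Cfb and Cfi, named after their values were seen) and 8 did not pass, also adjusted over the list alone (median -1.51, camera adjusted p = 0.106). Serping1, the C1 inhibitor, fell by 3.50 (SE 0.15, adjusted p = 9.98e-07) and C7, a part of the membrane attack complex, by 8.45 (SE 0.48, adjusted p = 2.74e-06).

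Checkpoint and suppression genes had 4 higher, 5 lower and 10 not past among 19 (3 and 5 adjusted over the list alone, median 0.16, camera adjusted p = 0.923). Arg1, arginase 1, rose from 1.78 to 86.6 CPM (SE 0.44, adjusted p = 1.4e-05), and Entpd1, the ectonucleotidase CD39, fell by 3.86 (SE 0.34, adjusted p = 2.68e-05). Lgals9, Havcr2 and Tigit rose and Vsir, Icos, Il10 and Cd86 fell, and Cd274, which encodes PD-L1, had a log2 change of -1.14 (adjusted p = 0.0909), all named after their values were seen. Of 26 interferon response genes 5 rose, 1 fell (Irf9, named after its value was seen) and 20 did not pass (4 rose adjusted over the list alone, median 0.28, camera adjusted p = 0.906). Mx1, an antiviral GTPase, rose by 3.29 (SE 0.72, adjusted p = 0.00379), and Irf7, the regulator of type I interferon genes, by 2.72 (SE 0.68, adjusted p = 0.00762) with overlapping groups and no call on log2(TPM + 1) (adjusted p = 0.0565) or with the replicate block (0.0738). Cxcl9, Oas1a and Usp18, named after their values were seen, were the others that rose. Of 15 genes of MHC class I presentation only H2-Q7 fell, by 2.40 (SE 0.68, adjusted p = 0.0132, 0.0527 without control 1, log2 change -3.04 without tumour-bearing 3), and its near copy H2-Q6 had -1.54 (adjusted p = 0.103), which passed in limma-voom, on log2(TPM + 1) and in 1 fit of all libraries (adjusted p = 0.0276, 0.0185 and 0.0451) and without tumour-bearing 3 (0.00226). Adjusted over the list alone edgeR called 0 (1 lower at an unadjusted p below 0.05, 1 in DESeq2, 3 in limma-voom), and median (0.24) and mean (-0.04) differed in sign under a downward test (camera adjusted p = 0.906). Immediate early genes fell in 12 of 18 cases and 6 did not pass, also adjusted over the list alone (median -2.51, camera adjusted p = 0.000252, adjusted p = 0.655 with an estimated correlation), with the transcription factor gene Jun at 1664 in control and 24.0 CPM in tumour-bearing lung (adjusted p = 1.56e-06). Among 13 mitochondrially encoded genes 1 rose, 4 fell and 8 did not pass (2 fell adjusted over the list alone, median -0.52, camera adjusted p = 0.465), with mt-Nd5, a subunit of complex I, at -1.61 (SE 0.39, adjusted p = 0.00667). Mt-Co3, which rose with overlapping groups, and mt-Nd2, mt-Nd4l and mt-Nd6, which fell, were named after their values were seen. Lists fixed for muscle did not pass in lung, apart from oxidative phosphorylation, with adjusted p from 0.0552 for satellite cell genes to 0.942 for the atrophy list. Satellite cell genes passed without control 1 or 2 or tumour-bearing 2, 3 or 5, and slow fibre genes (adjusted p = 0.0841) without tumour-bearing 2 or with the replicate block. In all, 17 of 41 lists passed, 4 higher and 13 lower, 27 passed in fry and 0 with an estimated correlation, and 17 of the 56 splits of the 8 libraries gave at least as many lists.

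**Figure D2:**
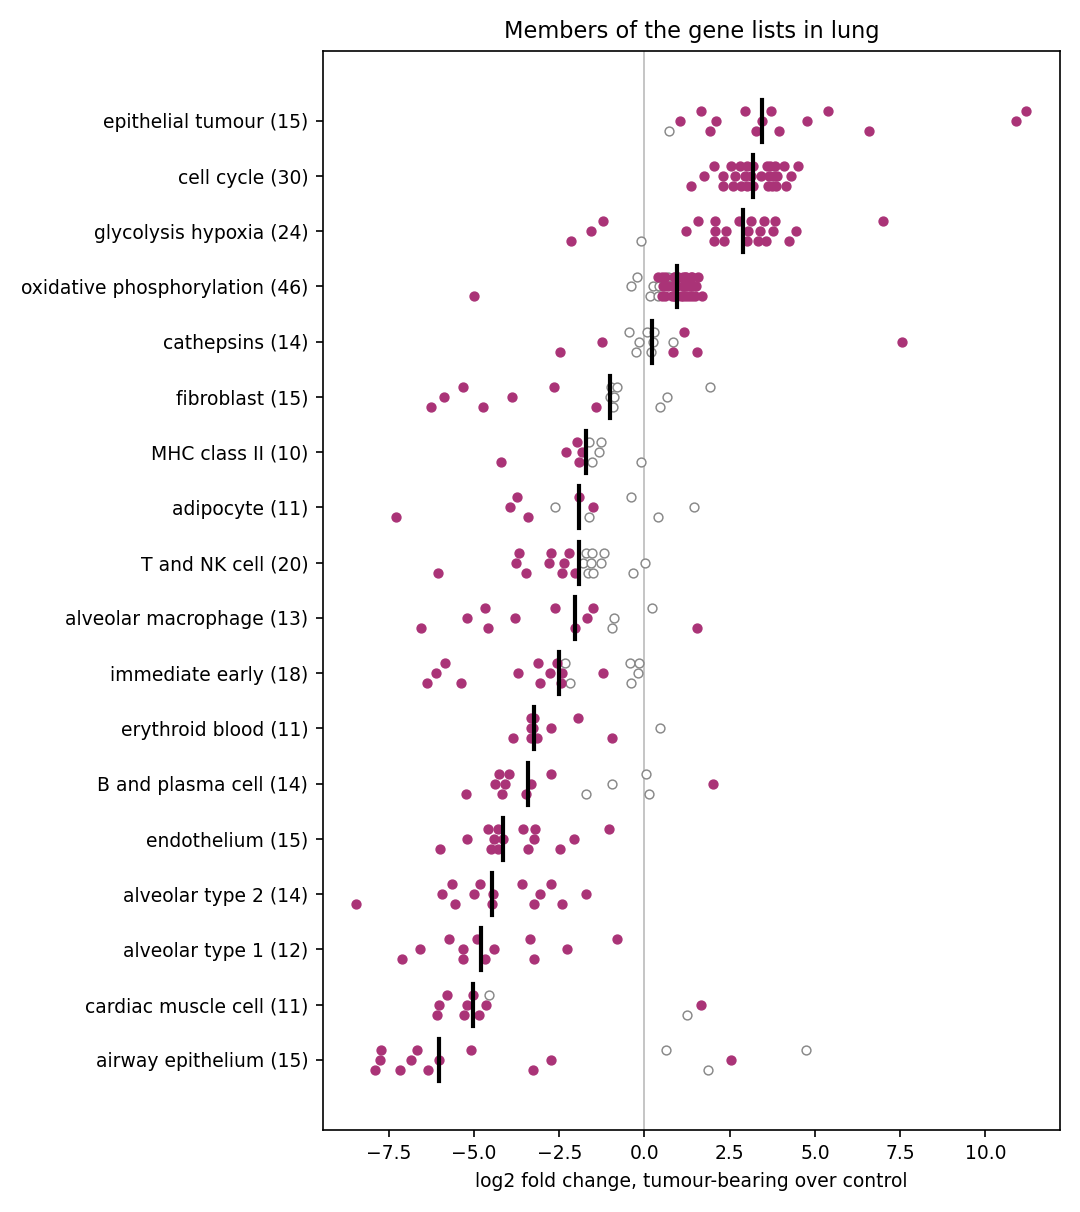
Log2 fold change of tested members of gene lists in lung, tumour-bearing over control (n = 5 and 3). Only the fixed lists that passed in camera at the preset correlation are shown, with the cathepsin list, which did not pass. Each gene is 1 point, filled where it passed the threshold, with a bar at the median of each list. Cell cycle genes have a median of 3.18 and endothelial genes of -4.14.

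To see which changes lung and muscle share, calls were compared over the 13885 genes tested in both tissues. Ctsl rose in both: in lung from 153 ± 4.87 to 449 ± 204 CPM, 2.93-fold (log2 change 1.55, SE 0.35, adjusted p = 0.0044, higher in all 5 tumour-bearing libraries), and in muscle 6.10-fold. The difference between its changes, lung minus muscle, was -1.05 (SE 0.66, adjusted p = 0.235) and did not pass, and on log2(TPM + 1) the lung change of 0.73 did not pass either (adjusted p = 0.0799). Y-linked genes summed to 8.65% of control CPM in tumour-bearing lung. Lung changes, that of Ctsl included, may thus come from a different mix of cells, which bulk RNA cannot tell apart from a response of lung cells. In both tissues 483 genes were higher (366 for independent lists) and 407 lower (244), while 237 were higher in muscle and lower in lung (330) and 186 the reverse (270). The 890 genes with the same direction became 92, 55 and 41 without muscle control 1, 2 or 3, and 439 and 1540 without muscle tumour-bearing 3 or 2. Fold changes correlated weakly across genes (Spearman 0.13, Pearson 0.14), and genes are not independent replicates.

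Among genes higher in both tissues were Psmd4 and Psma7, subunits of the proteasome that degrades ubiquitin-tagged proteins. Psmd4 changed by 2.54 in muscle and 1.33 in lung (interaction -1.21, adjusted p = 0.00882) and Psma7 by 1.97 and 1.72 (interaction -0.26, adjusted p = 0.531). Eif4ebp1 changed by 3.98 and 1.73 (interaction -2.24, adjusted p = 0.0028), and Fkbp5 by 3.52 and 1.85 (interaction -1.66, adjusted p = 0.0251). Lower in both were Ulk4 (-6.70 and -3.70, interaction adjusted p = 0.00219), the type VI collagen chains Col6a2 (-2.84 and -1.99, interaction 0.84, adjusted p = 0.0718) and Col6a3 (-2.96 and -1.21, interaction adjusted p = 0.00449), and Ssc5d (-3.70 and -2.52, interaction 1.16, adjusted p = 0.0647). Opposite directions were found for Glul, which rose in muscle (2.55) and fell in lung (-1.40, interaction adjusted p = 2.02e-05), and for Galnt15, a glycosyltransferase (3.39 and -4.27, interaction adjusted p = 4.02e-07), and Acer2, an alkaline ceramidase (3.30 and -4.13, interaction adjusted p = 5.46e-07). Map2k6, a kinase that activates p38, fell in muscle and rose in lung (-2.25 and 3.57, interaction adjusted p = 1.81e-06), as did the receptor phosphatase gene Ptprs (-2.50 and 1.22, interaction adjusted p = 1.28e-05) and the proprotein convertase gene Pcsk6 (-2.14 and 2.36, interaction adjusted p = 4.48e-06). Each of these genes separated the groups in both tissues. The interaction passed for 7057 of 19834 genes (5702 of them tested in both tissues), with 3287 changes higher in lung than in muscle and 3770 lower. In muscle, calls of Psma7 and Pcsk6 were lost without control 2 and that of Acer2 without control 3 (adjusted p = 0.0509, 0.0516 and 0.0502). The muscle calls of the 3 genes lower in muscle and higher in lung were lost on log2(TPM + 1) (adjusted p = 0.0630 for Map2k6, 0.182 for Ptprs and 0.126 for Pcsk6). Ptprs also lost its lung call there (0.0518).

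**Figure D3:**
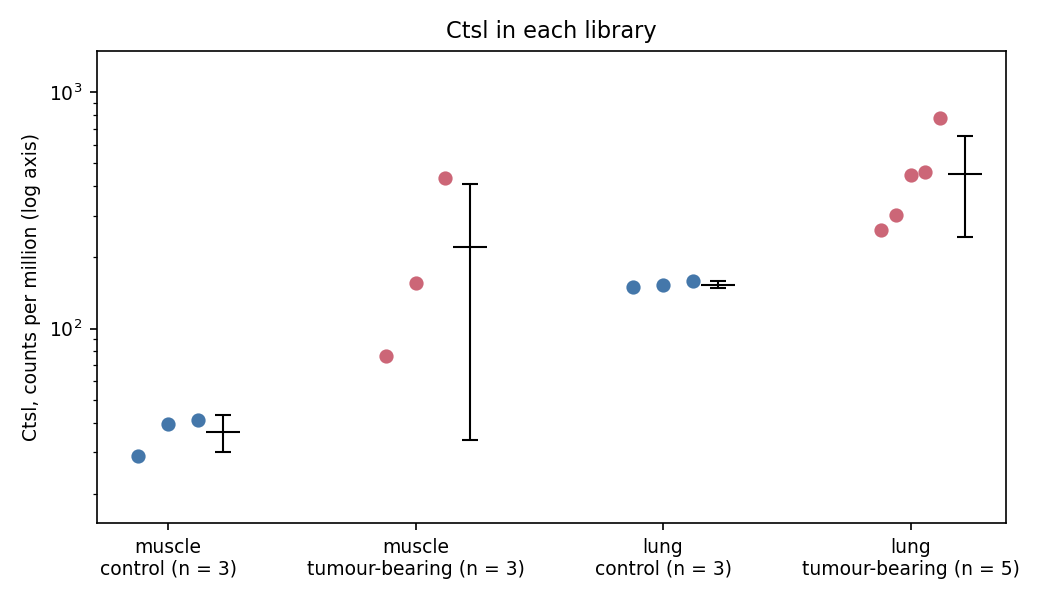
CPM of Ctsl in each library on a log axis, 1 point per library, with the mean and SD of each group (n = 3, 3, 3 and 5). Tumour-bearing libraries lie between 76.2 and 435 CPM in muscle and between 261 and 780 CPM in lung, all above the controls of their tissue.

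**Figure D4:**
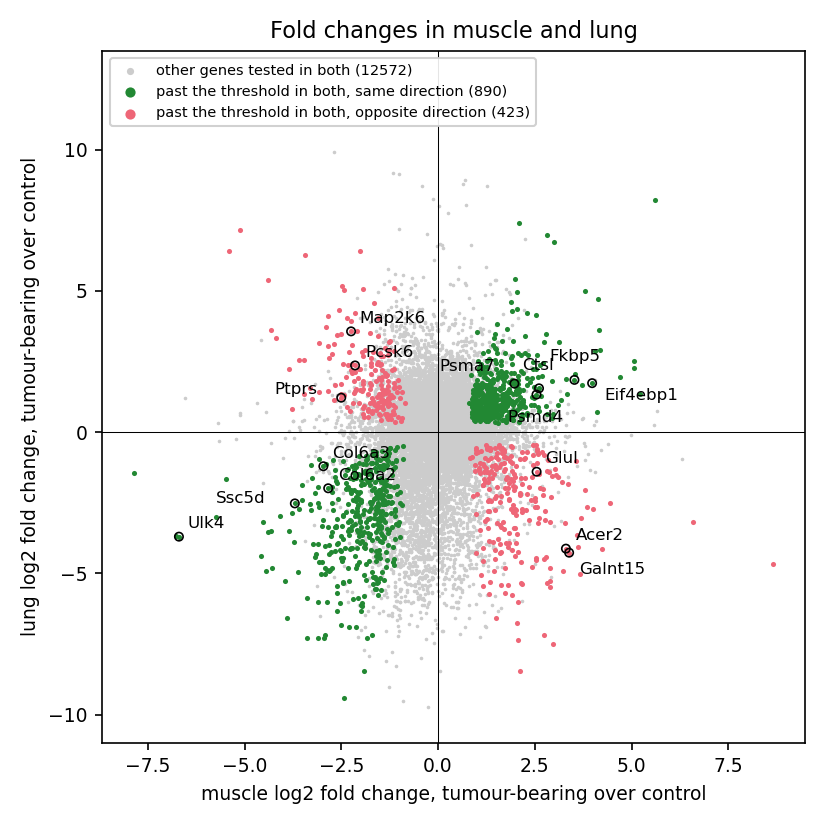
Log2 fold change in lung against log2 fold change in muscle, tumour-bearing over control, with 1 point per gene tested in both tissues, coloured by whether it passed in both with the same direction (890 genes), in both with opposite directions (423 genes) or not in both (12572 genes).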

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

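Of the tests below, those of Y-linked genes, of equal dilution, of Xist, of the mitochondrial share and of other cell types in muscle were chosen after the results were seen, as were the regroupings of 1 tissue with the other held, while those of scaling, of fibroblast markers and of the other splits were set before.

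A single library stood far from the other 4 in tumour-bearing lung for 8 of 69 items, 62 named genes and 7 measures of library quality, tested by Dixon's ratio of gap to range, a test that chance passes in about 1 of 20 groups. All 8 were genes. Library 3 was high for Cyp1a1 (0.187 against at most 0.0207 CPM, ratio 0.890) and H2-Q6 (113 against 6.19 to 30.4 CPM, ratio 0.773). Library 2 was high for Myl4 (8.18 against 0.392 to 0.818 CPM, ratio 0.945), Slc7a10 (0.0992 against at most 0.0170 CPM, ratio 0.828) and Ube2c (78.1 against 43.0 to 51.1 CPM, ratio 0.770). Library 5 was high for Prl2c2 (1085 against 27.3 to 189.6 CPM, ratio 0.847) and Prl2c3 (2015 against 49.6 to 441 CPM, ratio 0.801) and low for Tnni2 (8.39 CPM, with the others up to 17.1, ratio 0.760).

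The change with tumour differed between lung and muscle, by the edgeR interaction, for 11 of the 15 genes named in both tissues. This share is partly fixed by the rule, which took Map2k6, Ptprs, Pcsk6, Glul, Galnt15 and Acer2 from genes that passed the interaction. Genes named in 1 tissue are not counted here. Lung minus muscle, the differences in log2 change were -2.24 for Eif4ebp1, -1.21 for Psmd4, -1.66 for Fkbp5, 3.03 for Ulk4, 1.74 for Col6a3, 5.80 for Map2k6, 3.70 for Ptprs, 4.50 for Pcsk6, -3.945 for Glul, -7.64 for Galnt15 and -7.41 for Acer2. It also differed for 6 gene lists in camera, none of which passed with an estimated correlation. Collagen genes were relatively higher in lung (adjusted p = 0.0045, adjusted p = 0.640 with an estimated correlation). Relatively lower in lung were T and NK cell genes (0.00713, adjusted p = 0.640 with an estimated correlation), neutrophil genes (0.00713, adjusted p = 0.468 with an estimated correlation) and endothelial genes (3.83e-08, adjusted p = 0.463 with an estimated correlation). In muscle just 3 of the 20 T and NK cell genes and 5 of the 15 neutrophil genes had enough counts to be tested, so for most members of these 2 lists no muscle change was measured. Also relatively lower in lung were erythroid genes (0.0406, adjusted p = 0.640 with an estimated correlation) and immediate early genes (0.000129, adjusted p = 0.468 with an estimated correlation).

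Markers of alveolar, airway and endothelial cells were far lower in tumour-bearing lung. Scaling is argued against as a cause, since the endothelial median nearest to 0 among 4 scalings was -4.14. Equal dilution of every host cell type as the whole cause is argued against too. The lower quartile of macrophage and monocyte genes was -1.24, above the highest change among the 4 Y-linked genes, -2.82. The 4 Y-linked genes of these male mice had a median of -3.59 (from -3.86 to -2.82) and summed to 8.65% of control CPM, which is consistent with RNA from cells without a Y chromosome making up much of these libraries. Growth of the injected cells may be their source, a hypothesis that was found and tested on the same data, and a loss of some host cell types beyond dilution stays open as well.

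Xist, the RNA that female cells use to silence an X chromosome, had 1171, 743, 9.12, 608 and 23.1 CPM in the 5 tumour-bearing lung libraries and 0.916 to 1.08 CPM in the 3 controls. The labels give male mice, and libraries from female mice alone are argued against because the lowest summed count of Y-linked genes was 471. The highest Xist level was 128-fold the lowest among these 5 libraries, whereas summed Y-linked CPM, from 9.12 to 20.7, differed by 2.26-fold. Xist expression by the injected cells, at levels that differ between libraries, could account for this, but it cannot be told apart from other sources because no library of the injected cells is among the 14.

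Collagen and fibroblast genes were lower in tumour-bearing muscle. The share of counts on mitochondrial genes and their nuclear copies is argued against as the whole cause. Between a tumour-bearing and a control library it gave other genes a log2 shift of -0.26 at the lowest, whereas the collagen list had an upper quartile of -0.59. A lower share of every non-muscle cell type alike is argued against by the neutrophil median of 2.48 (quartiles 1.92 and 2.63), although a rise of neutrophils themselves stays open. Of the 4 other cell types, 3 had medians above the fibroblast upper quartile of -0.50, namely neutrophil, endothelial (-0.20) and macrophage genes (-0.08), the last 2 with quartiles that overlap those of fibroblasts. Schwann cell and nerve genes, at -0.80, went with a lower share. Fewer fibroblasts cannot be told apart from lower matrix expression per cell, because fibroblast markers that are not matrix genes had a median of -0.56 with members going apart. Pi16, Thy1 and Fap fell (-3.73, -3.16 and -1.51), whereas Pdgfra, Gli1, Acta2 and Pdgfrb did not pass (-0.56, -0.48, -0.30 and -0.02).

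Other splits of the same libraries were run as a check against chance. For the 2196 muscle genes the 10 splits are too few for a share below 0.05, and the highest other split gave 0 genes, while 1 split, the real one, gave as many as 2196. For the 11513 lung genes 1 of 56 splits, the real one, gave as many and the highest other gave 14. This argues against group labels that fell on these libraries at random. Chance differences between animals are not excluded, because the labels do not say that the libraries come from separate animals. With muscle held at its real groups, 1 of 56 lung groupings gave the 890 genes with the same direction in both tissues and the highest other 0. This says little about sharing, because the other lung splits gave at most 14 calls. Groupings of both tissues were also drawn at random, with the real one put into each set. Of 100 groupings only the real one gave 890 shared genes, and the highest other gave 0. This says little because muscle gave 0 calls in every other split. Of 40 groupings only the real one gave 7057 interaction genes, and the highest other gave 689. That argues only against both groupings being by chance. So muscle libraries were regrouped with lung held, and the 20 regroupings are too few for a share below 0.05. Against 890 genes with the same direction the highest other gave 423, with the 2 muscle groups exchanged. Against 7057 interaction genes 2 regroupings gave as many, the real one included, and the highest other gave 8192, also with the groups exchanged. The other 18 gave 3975 to 5882 interaction genes, so that much of this count comes with the lung groups alone. For the 11 muscle lists chance cannot be excluded, since 4 of 10 splits, the real one included, gave as many and the highest other gave 15. For the 17 lung lists chance cannot be excluded, since 17 of 56 splits gave as many and the highest other gave 24. In both tissues the other splits mix the real groups unevenly and keep part of their difference. For lists these splits therefore cannot decide for or against chance.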

How the results depend on the processing

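Of the settings below, the fit without mitochondrial genes was chosen after the data were seen and all others before. No named gene and no list past the threshold reversed its direction. Upper-quartile scaling turned the medians of the cathepsin, fast fibre, fatty acid oxidation, MHC class II, alveolar type 2 and clock lists in muscle and of the atrophy and macrophage lists in lung. RLE also turned that of the last, and none of these lists was past the threshold. The balance of muscle genes turned to more lower than higher with upper-quartile scaling, limma-voom (1001 and 1110), log2(TPM + 1) and the replicate block. That of lung turned with RLE (5603 higher and 5782 lower) and 6 other settings. In each tissue it also turned without any 1 of the controls. Where a value moved, the cause was not tested, except that fits without a library have fewer samples and the filters set how many genes are tested. The replicate block also takes its lung changes from tumour-bearing 1 to 3 alone. Muscle counts moved most: against 2196 genes (1226 higher, 970 lower), DESeq2 gave 3658 (2093 and 1565), log2(TPM + 1) 415 (157 and 258), no filter 4031 (2253 and 1778), 1 fit of all libraries 3459 (1881 and 1578), and upper-quartile scaling 760 higher and 1079 lower. Of the 2196, DESeq2 shared 2184 and the unfiltered fit 2121 with the same sign. In lung, log2(TPM + 1) called 3594 higher and 7994 lower genes. Genes with the same direction in both tissues numbered 1417 in DESeq2, 161 on log2(TPM + 1) and 1343 with no filter, and the correlation between tissues was 0.0924, 0.104 (no filter) and 0.104 (mean of at least 1 CPM) where it moved. On log2(TPM + 1) the Ctsl calls were lost at 0.73 in lung and 2.74 in muscle. With an estimated correlation 0 lists passed in each tissue, and in fry 5 in muscle and 27 in lung. Without mitochondrial genes 2203 muscle and 11505 lung genes passed.

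Leaving out 1 library at a time gave 106 (without control 3) to 4513 (without tumour-bearing 2) muscle genes, 33 to 2447 higher and 73 to 2066 lower, and 41 to 1540 genes with the same direction in both tissues. In lung it gave 9405 to 11674 genes, 4526 to 6008 higher and 4879 to 5674 lower, and for the interaction 5703 to 7641. The correlation between tissues ran from 0.103 to 0.174, Ctsl from 1.69 to 3.05 in muscle and 1.29 to 1.71 in lung, and the lists past the threshold from 10 to 14 in muscle and 15 to 19 in lung. Of 55 genes named in muscle, Ctsl included, 22, 26 and 30 lost their call without control 1, 2 or 3, and 8, 2 and 11 without tumour-bearing 1, 2 or 3. On log2(TPM + 1) 23 lost it. Of 62 named in lung at most 3 did under any setting, and these were Ctsl, Ptprs and Irf7 on log2(TPM + 1).

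In lung replicate numbers showed no pairing: correlations of same-numbered deviations ran from -0.00 to 0.06 (0 of 3 above 0.1, 1 of 3 best with their own number). In muscle they ran from -0.05 to 0.37 (2 of 3 above 0.1, 2 of 3 best), and with 3 pairs a pairing there stays open. With the replicate block 3303 muscle genes passed (1676 lower) and 10298 lung genes, Ctsl had 2.27 in muscle and 1.09 in lung, and among named genes Irf7 in lung alone lost its call. Lung controls have replicate numbers 1 to 3 only, so tumour-bearing lung 4 and 5 each had a block to themselves. The blocked lung changes thus rest on tumour-bearing 1 to 3 and differ from the main fit by more than a pairing. Depth sets a floor of 3 counts per library, and simulations recovered 2% of 2-fold changes in muscle and 11% in lung. They gave 68 and 93 calls, against 2196 and 11513 in the real data, so their adjusted threshold was stricter. These percentages therefore cannot tell how many changes of that size the real tests missed. In lung, only 4203 higher and 4895 lower of the 11513 genes called changed over 2-fold, so smaller changes were called too.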

Other observations

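The 5 gene lists below and the genes named from them were chosen after the data were seen, so their tests are not independent evidence.

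Proteasome subunits were higher in both tissues. Of 32 tested, 26 rose in muscle and 6 did not pass (29 adjusted over the list alone, median 1.29, camera adjusted p = 1.02e-15, adjusted p = 0.103 with an estimated correlation), and 30 rose in lung, also adjusted over the list alone (median 1.05, camera adjusted p = 2.44e-08, adjusted p = 0.326 with an estimated correlation). Among them were Psmd4 and Psma7. All 60 cytosolic ribosomal protein genes rose in lung, also adjusted over the list alone (median 1.96, camera adjusted p = 7.1e-22, adjusted p = 0.326 with an estimated correlation). In muscle 4 of 60 rose and 56 did not pass (2 adjusted over the list alone, median 0.55, camera adjusted p = 8.43e-07, adjusted p = 0.572 with an estimated correlation). Clock genes did not pass as a list in muscle, with 5 of 16 higher, 2 lower and 9 not past (5 and 3 adjusted over the list alone, median 0.17, camera adjusted p = 0.452), a median that upper-quartile scaling turned to -0.07. Per1, Cry2, Ciart, Per2 and Tef rose and Bhlhe41 and Npas2 fell, with log2 changes of 3.05 for Per1, a period gene that glucocorticoids also induce, and 3.06 for the cryptochrome gene Cry2. In lung Bhlhe40 rose and Hlf, Npas2, Nr1d1 and Clock fell, while 11 did not pass (1 and 3 adjusted over the list alone, median -0.68, camera adjusted p = 0.134).

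Tumour-bearing lung also held RNA of genes typical of gut and liver epithelium. Of 30 tested, 19 rose, 2 fell and 9 did not pass (19 and 3 adjusted over the list alone, median 6.31, or 5.80 with Apoa4, which had no control count, at its bound, camera adjusted p = 0.000304, adjusted p = 0.326 with an estimated correlation). Hnf4a, a transcription factor of liver and gut epithelium, rose from 0.866 to 189 CPM (log2 change 7.77, adjusted p = 7.05e-07), and Lgals4, a galectin of the gut, changed by 6.63. Fabp1 and Pgc fell. Other lists held 3 of these genes, Fabp1, Muc1 and Muc5ac. In muscle 3 of these genes were tested and edgeR called 0 (0 at an unadjusted p below 0.05, 0 in DESeq2), and of 4 Y-linked genes it called 0 as well (1 higher at an unadjusted p below 0.05, 0 in DESeq2, median 0.51).

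Ctsl was highest in the libraries tumour-bearing 1 of muscle (435 CPM) and tumour-bearing 5 of lung (780 CPM), and without these the log2 changes were 1.69 and 1.29.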
